A study of Mus musculus with 11 samples.

How the data were processed

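Aortic valves of wild type mice were profiled by RNA sequencing 48 hours after surgery, with 1 mouse per library. Per the labels' protocols, a wire was used in vivo to damage the endothelial layer of the valve, and sham surgery served as the control procedure. Young mice were 3 to 4 months old and aging mice 16 to 18 months old. The 11 libraries fell into 4 groups by age and surgery, with 3 young sham, 3 young injured, 3 aging sham and 2 aging injured mice. Per the labels' protocols, total RNA was extracted from frozen valves, treated with DNase and made into libraries from 200 ng with an mRNA library kit, and sequenced with 150 nt paired-end reads.

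Per the submitters' processing notes, the work used the mm10 genome build and TopHat2 version 2.1.0. The counting program, its use of strand and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical gene copies cannot be assigned with certainty. The authors deposited raw counts for 46983 genes with Ensembl identifiers and gene coordinates, mitochondrial genes included, with no normalization. The authors also deposited RPKM values for 13526 genes, of which 13473 were protein-coding and 0 were mitochondrial. In the highly counted genes the RPKM values followed the library totals without mitochondrial genes to within 0.25%, and the totals with them to within 5.57%. In 4 libraries the lowest RPKM value was repeated in 72 to 273 genes, so low values there stand at a minimum and not at a measurement. Among the library columns of the counts, 1 matched no sample label and was used in no step.

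Totals ranged from 27124000 to 36353474 counts per library, and scaled values are given as CPM. Mitochondrial genes took 5.10% to 13.78% of the counts. Each library came from its own mouse and was counted as 1 replicate. As a check for the same library deposited more than once within a group, the counts of the 10 pairs of libraries of the same group were compared by a chi-square test over genes, and the statistic per degree of freedom ranged from 22.6 to 250.9. Intervals from counts, and the bound of 3 counts used where a group had 0, cover counting error only.

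The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were kept by the filterByExpr function with its minimum count of 10, which left 19366 genes. Library sizes were scaled by the trimmed mean of M values (TMM), and all 11 libraries entered 1 fit with 4 group means and no covariate, so that all groups shared the estimate of the spread. The common biological coefficient of variation was 0.377. The comparisons were injury in young valves, injury in aging valves, age in sham valves, age in injured valves, the injury by age interaction, and injury averaged over age. A gene was called as changed at a Benjamini-Hochberg adjusted p under 0.1 and a fold change over 2, the thresholds that the series' own design text gives. The words rose and fell are used for genes past both. Standard errors (SE) of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F.

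A total of 29 gene lists holding 567 genes were fixed together with the tests, the alternatives and the rule for named genes before the data were examined. The lists were cell cycle, neutrophil, monocyte and macrophage, lymphocyte, cytokine and chemokine, interferon-stimulated, coagulation and fibrinolysis, pan-endothelial, valve endothelial and shear-responsive, leukocyte adhesion, mesenchymal transition and myofibroblast, collagen and elastic fibre, proteoglycan and hyaluronan, matrix protease, osteochondrogenic, antioxidant, hypoxia and glycolysis, oxidative phosphorylation, immediate early and heat shock, senescence-associated, unfolded protein response, cardiomyocyte, smooth muscle, adipocyte, erythroid and platelet, melanocyte, Schwann cell, mesothelial, and fibroblast genes. Each list was tested against the other genes with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, with adjustment over the lists of a comparison and a threshold of 0.1. Camera with a correlation estimated per list and the rotation test fry, which asks whether a list's genes move on balance one way, were run beside it. With the estimated correlation the cell cycle list held its call for injury in young valves and for injury averaged over age, and no other call held. Of the 75 calls of lists, 1 had a mean opposite in sign to its median and test, namely the senescence-associated genes after injury in aging valves, with a median log2 fold change of 0.18 and a mean of -0.07. List medians with and without a library or under another setting were taken from the log2 CPM values that camera tests, and other list medians from the edgeR log2 fold changes. List medians were computed again with members counted at 0 in a whole group set to their bound, and 0 medians moved.

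Named genes were, per comparison, the 10 genes that rose and the 10 that fell with the smallest p among called genes, leaving out clone-like symbols and antigen receptor segments, or the 5 with the smallest p where no gene was called. Some genes that this rule names are not reported here. For each list, up to 4 members with the smallest p were named, and for lists of cell type markers also the 2 most abundant members. The test was first run on simulated counts drawn from the libraries' own means and sizes. Changes were put only into genes with a mean above 1 CPM, so the shares recovered do not cover genes below that level. For injury in young valves, with 18770 genes in the simulation, 76% of the changes of 1.5 and 96% of the changes of 3 on the log2 scale were recovered, with 12 false calls among 184. For injury in aging valves, with 18773 genes, the shares were 68% and 86%, with 9 false calls among 163. Apart from the changes put in, each gene was drawn with the same mean and spread in all libraries. The simulation thus gave no wider scatter to the libraries with fewer detected genes described below. Both aging injured libraries are among them, so the shares for aging valves may be too high.

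The alternatives chosen before the data were examined were other scalings (DESeq2 size factors and upper quartile), other filters on low counts, DESeq2 1.42.0, limma-voom, robust dispersions, limma on the logarithm of the deposited RPKM plus 0.1 or plus 1, counts without mitochondrial genes, fits with only the groups compared, the replicate number as a block, the cardiomyocyte marker score as a covariate, other thresholds, and leaving out each library in turn. Added after seeing the data were the sex of the mouse as a covariate, a term for 3 libraries with fewer detected genes, and library quality weights in limma-voom. Sex was read from Xist and from Ddx3y, Eif2s3y, Kdm5d and Uty.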

Results

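Gene expression was measured in whole aortic valves of young and aging mice 48 hours after wire injury or sham surgery. Young sham, young injured and aging sham valves were each represented by 3 mice, and aging injured valves by 2. Total counts ranged from 27285385 to 36009433 in young sham, from 33179445 to 34652712 in young injured, from 27124000 to 36353474 in aging sham, and were 28052207 and 34715421 in aging injured libraries. Of the 46983 genes counted, 19366 were tested. Values are TMM-scaled CPM from the deposited counts, and adjusted p-values come from edgeR's quasi-likelihood test unless another tool is named.

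Some measured properties differed between libraries of the same group. Young sham 1 and both aging injured libraries held counts for 18641, 18642 and 19015 genes, and the other 8 libraries for 20411 to 22533. Cardiac muscle transcripts were present in every library. Myh6, the main myosin heavy chain of the mouse atrium and ventricle, stood at 9535 ± 2631 CPM in young sham (SD, n = 3), 5448 ± 3877 in young injured (n = 3), 4529 ± 2429 in aging sham (n = 3) and 5185 ± 306 CPM in aging injured valves (n = 2). The mean of the cardiomyocyte marker list, on the log2 scale relative to all libraries, was -0.80 and -0.83 in young injured 1 and 2 and 1.43 in young injured 3. By Xist and Y-linked transcripts, young sham held 2 males and 1 female, young injured 1 male and 2 females, aging sham 1 male and 2 females, and aging injured 0 males and 2 females.

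The first comparison asked what injury changed in young valves. After injury 78 genes rose and 3 fell, and 3 of the 10 rising genes with the smallest p, clone-like symbols left out, were on the cell cycle list. Ccna2, which encodes cyclin A2 (ENSMUSG00000027715, chromosome 3, 36564865 to 36572150 in mm10), stood at 1.51 ± 0.32 CPM in sham and 20.1 ± 6.33 CPM in injured valves (SD, n = 3 each). Its change was 13.3-fold, or 3.73 ± 0.38 on the log2 scale (SE), with an adjusted p of 0.0054. Top2a, the DNA topoisomerase of dividing cells (chromosome 11, 98992943 to 99024189), rose 9.82-fold, from 4.32 ± 1.53 to 42.5 ± 12.9 CPM (n = 3 each). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, rose 14.4-fold and Aspm, a spindle protein, 8.81-fold. Uhrf1, which maintains DNA methylation at replication, rose 6.37-fold. Fam83d, another spindle protein, had 1 count over the 3 sham libraries and 356 over the 3 injured ones, a ratio of 316 with an exact 95% interval of 56.4 to 12500.

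Of the 43 cell cycle genes, 17 rose over all genes tested and 38 adjusted over the list alone, and 43 had a positive log2 fold change with a median of 2.13. The list went up against the other genes (camera adjusted p = 7.43e-42, and adjusted p = 0.0931 with an estimated correlation). Kif20a, a mitotic kinesin, rose by 3.14 ± 0.41 on the log2 scale. The list scores of the 3 injured libraries were 0.92, 1.80 and 1.19, above the sham values of -0.52, -0.91 and -1.07.

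**Figure D1:**
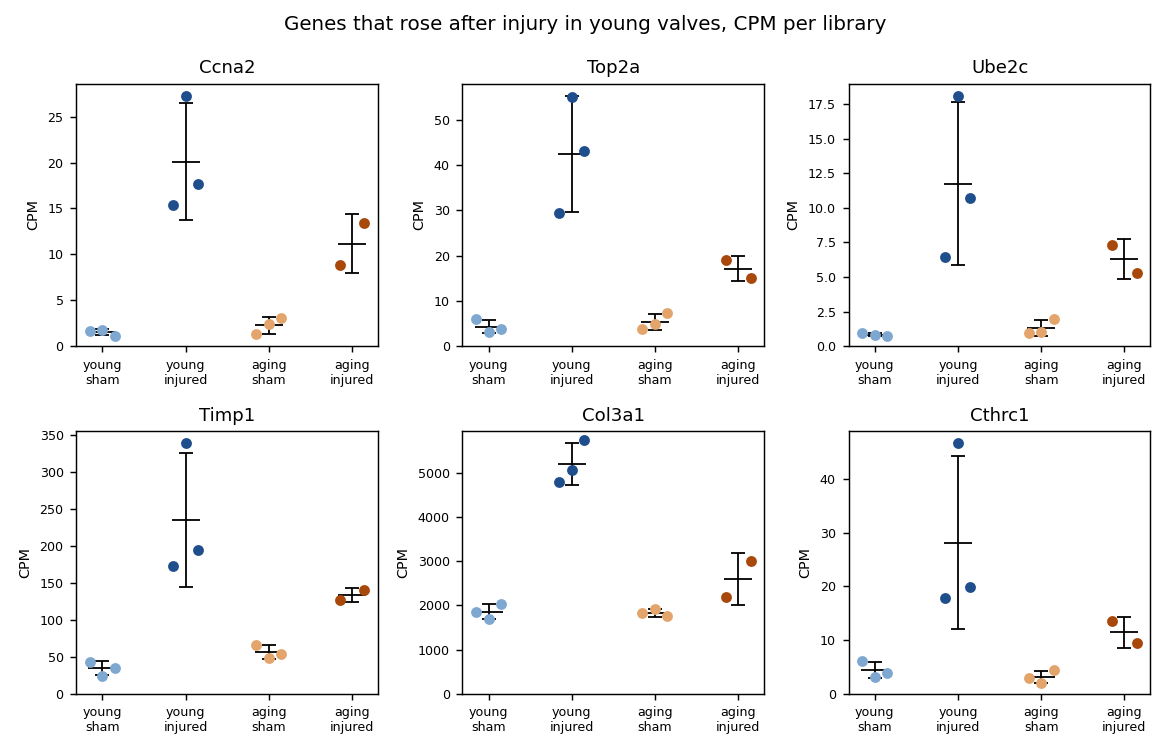
CPM (linear axis) of 6 genes that rose after injury in young valves, by group, where points are libraries and bars give the mean and SD of 3 libraries, or of 2 for aging injured. Ccna2 averaged 20.1 CPM in young injured and 1.51 CPM in young sham valves, and 11.2 CPM in aging injured and 2.27 CPM in aging sham valves.

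Genes of the extracellular matrix formed another group. Timp1, a secreted inhibitor of matrix metalloproteinases (chromosome X, 20870166 to 20874735), rose 6.84-fold, from 34.4 ± 9.51 to 235 ± 90.5 CPM (n = 3 each), with an adjusted p of 0.0054. Col3a1, the chain of type III collagen (chromosome 1, 45311538 to 45349706), rose 2.80-fold, from 1860 ± 163 to 5201 ± 481 CPM (n = 3 each). Among the 24 collagens and elastic fibre genes 4 rose, or 5 adjusted over the list alone, and Col5a2 and Col6a3 were among them at 1.09 ± 0.16 and 1.02 ± 0.15 on the log2 scale. The median of that list was 0.69 (camera adjusted p = 3.88e-10, but adjusted p = 0.371 with an estimated correlation). Of the 27 matrix proteases, inhibitors and crosslinking enzymes, 2 rose, Timp1 and the membrane protease gene Mmp14, or 6 adjusted over the list alone (median 0.42, camera adjusted p = 5.35e-06, adjusted p = 0.376 with an estimated correlation). Of the 23 mesenchymal transition and myofibroblast genes 3 rose, both over all genes and adjusted over the list alone. These were Tnc, which encodes the matrix protein tenascin C, Cthrc1, a secreted protein of activated fibroblasts, and Inhba, the activin A subunit, at 1.44 ± 0.23, 2.67 ± 0.43 and 1.52 ± 0.27 on the log2 scale. The median of that list was 0.26 (camera adjusted p = 0.00609, adjusted p = 0.592 with an estimated correlation). Among the 21 proteoglycan and hyaluronan genes 1 rose, Vcan, which encodes versican, and the list did not pass (median 0.13, camera adjusted p = 0.524). The mesenchymal median on the log2 CPM scale was 0.22, the list did not pass without young sham 3 (0.22), and the median was 0.36 without young sham 2 and 0.52 without young injured 3. Dclk1, a microtubule-associated kinase, rose 2.12-fold, and Fam111a, a replication-associated protease, 2.28-fold.

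Cytokine, monocyte and macrophage, and leukocyte adhesion lists passed upward by the preset test, with few single genes past the threshold, and neutrophil, lymphocyte and interferon-stimulated lists did not pass. Young injured 2 had the highest scores, with -0.08, 1.33 and 0.30 for cytokines, -0.31, 0.67 and 0.01 for monocytes and macrophages, and -0.05, 0.78 and -0.07 for leukocyte adhesion in young injured 1, 2 and 3. On the log2 CPM scale, without young injured 2 the monocyte and macrophage list did not pass, with a median of 0.16 against 0.36 with all libraries, and the cytokine median was 0.34 against 0.57. Without young injured 1 these medians were 0.57 and 1.00, and the cytokine median was 1.00 without young sham 3. Of 25 cytokines and chemokines 1 rose, Lif, a cytokine of the interleukin-6 family, at 1.87 ± 0.32 on the log2 scale. Adjusted over the list alone 4 did, and 23 had positive log2 fold changes (median 0.63, camera adjusted p = 5.08e-05, adjusted p = 0.466 with an estimated correlation). The monocyte chemoattractant Ccl2 did not pass, at 2.36 ± 0.51 with an adjusted p of 0.101. Of 25 monocyte and macrophage markers 0 passed in the edgeR test over all genes and 2 adjusted over the list alone, Ccr2 and Cd68, and the list median was 0.37 (camera adjusted p = 0.000705, adjusted p = 0.654 with an estimated correlation). The most abundant of these markers, Lyz2 and Csf1r, stood at 0.37 ± 0.23 and 0.10 ± 0.20. Of the 10 leukocyte adhesion molecules 0 passed over all genes and 4 adjusted over the list alone, led by Vcam1 at 1.07 ± 0.24 (median 0.75, camera adjusted p = 0.000675, adjusted p = 0.398 with an estimated correlation). The coagulation and fibrinolysis list had a median of 0.36 (camera adjusted p = 0.00645, adjusted p = 0.592 with an estimated correlation), with 0 of 16 members called over all genes and 2 adjusted over the list alone, Procr, the endothelial protein C receptor, and Plaur, the urokinase receptor, at 2.08 ± 0.54 and 1.48 ± 0.42. Anxa2 and S100a10, the subunits of a plasminogen receptor, were under 2-fold at 0.93 ± 0.15 and 0.99 ± 0.17. The coagulation median on the log2 CPM scale was 0.37, it was 0.19 without young sham 2, and the list did not pass without young injured 3 (0.32). Of the 19 unfolded protein response genes 16 were positive and 1 was up adjusted over the list alone (median 0.49, camera adjusted p = 5.99e-07, adjusted p = 0.376 with an estimated correlation). The chaperones Pdia4 and Manf stood at 0.78 ± 0.12 and 0.87 ± 0.16, with adjusted p-values of 0.0264 and 0.0622 and under 2-fold.

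The lists that went down by the preset test held no called gene. All 28 oxidative phosphorylation and fatty acid oxidation genes were negative (median -0.52, camera adjusted p = 3.94e-09, adjusted p = 0.592 with an estimated correlation), with Ppargc1a at -1.13 ± 0.46. Of the 26 cardiomyocyte markers 2 were positive (median -0.72, camera adjusted p = 4.58e-07, adjusted p = 0.592 with an estimated correlation), with Hrc at -1.13 ± 0.55, Myh6 at -0.81 ± 0.47 and Myh7 at -0.49 ± 0.84. Both lists differed between the injured libraries, with oxidative phosphorylation scores of -0.70 and -0.48 in young injured 1 and 2 and 0.78 in young injured 3, where the cardiomyocyte scores were -0.80, -0.83 and 1.43. On the log2 CPM scale the oxidative phosphorylation median was -0.65, and -0.35, -1.09 and -0.43 without young injured 1, young injured 3 and young sham 3. The cardiomyocyte median was -1.03, and -0.62, -0.68 and -1.73 without young injured 1, 2 and 3. The 10 Schwann cell markers were all negative (median -0.54, camera adjusted p = 0.000675, adjusted p = 0.398 with an estimated correlation), led by Mbp, a myelin protein, at -0.82 ± 0.21. The 14 smooth muscle markers had a median of -0.25 (camera adjusted p = 0.0115, adjusted p = 0.654 with an estimated correlation) and the 23 pan-endothelial markers a median of -0.23 (camera adjusted p = 0.0959, adjusted p = 0.932 with an estimated correlation), with Eng at 0.14 ± 0.27 and Pecam1 at 0.04 ± 0.32. Young injured 1 scored -1.08 for pan-endothelial markers, and young injured 2 and 3 scored 0.18 and 0.35. The pan-endothelial median on the log2 CPM scale, -0.29 with all libraries, turned to 0.14 without young injured 1 and was -0.08 without young sham 3, -0.45 without young sham 1, -0.52 without young injured 2 and -0.49 without young injured 3. That list also did not pass without aging sham 1 (-0.29), 2 (-0.30) or 3 (-0.29) or without aging injured 1 (-0.30) or 2 (-0.29). The smooth muscle median, -0.28 with all libraries, turned to 0.02 without young injured 3 and was -0.05 without young sham 1, neither past the threshold, -0.64 without young sham 3 and -0.56 without young injured 1. It was -0.05, not past the threshold, with the term for 3 libraries described below. The Schwann cell median was -0.45, and -0.78 without young sham 1. The 11 mesothelial markers had a median of 0.59 (camera adjusted p = 0.0328, adjusted p = 0.667 with an estimated correlation), and did not pass without young sham 3 or young injured 2, with log2 CPM medians of 0.24 and 0.22 against 0.79. Among the 3 genes that fell were Cntfr, the receptor of ciliary neurotrophic factor, at -1.54 ± 0.30, and the matrix protein gene Coch at -1.70 ± 0.35.

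The remaining lists did not pass for injury in young valves. Their medians were 1.29 for neutrophil markers, -0.27 for lymphocyte markers, 0.03 for interferon-stimulated genes, 0.05 for valve endothelial and shear-responsive genes, -0.02 for osteochondrogenic genes, 0.14 for antioxidant genes, and -0.08 for hypoxia and glycolysis genes. They were -0.40 for immediate early and heat shock genes, 0.24 for senescence-associated genes, 0.53 for adipocyte, -0.01 for erythroid and platelet, 0.12 for melanocyte and 0.13 for fibroblast markers. The count of 81 called genes rested on single libraries. It was 16 without young injured 2, 20 without young sham 2, 41 without young sham 1, 48 without young sham 3, 48 without aging sham 2, 53 without aging sham 3, and 447 without young injured 3, the library with the highest cardiomyocyte score among the injured ones. Of those 447 genes 137 rose and 310 fell, so the balance of directions turned without that library. With library quality weights, a setting added after seeing the data, 249 rose and 127 fell. The count was 268 with DESeq2, 11 when only the young libraries were fitted, and 43 with a term for the 3 libraries with fewer detected genes, a term added after seeing the data, with 31 of these among the 81. With the cardiomyocyte score as a covariate it was 72, with 59 of these among the 81, and 12 of the 15 lists stayed past the threshold. The cardiomyocyte list is 1 of the 15, and as it supplies the score its own result there was set by construction.

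The same injury in aging valves gave 0 called genes with edgeR, and 1710 genes had an unadjusted p under 0.05. DESeq2 called 329 genes, 72 up and 257 down, and limma-voom 0, and edgeR called 261 without aging injured 1, 47 up and 214 down. The 5 genes with the smallest p did not pass. Ccna2 stood at 2.30 ± 0.38 on the log2 scale (SE), from 2.27 ± 0.92 CPM in sham (n = 3) to 11.2 ± 3.21 CPM in injured valves (n = 2), and its adjusted p was 0.258. Zfp442, a zinc finger gene, had 210 counts over the sham and 1 over the injured libraries, a ratio of 135 with an exact 95% interval of 24.0 to 5360 (adjusted p = 0.148). Med31, a subunit of the Mediator complex, stood at -2.03 ± 0.30, Dhodh, an enzyme of pyrimidine synthesis, at -1.24 ± 0.21, and Traf4, a signalling adaptor, at 1.23 ± 0.19, with adjusted p-values of 0.253, 0.258 and 0.253. Both injured libraries of this comparison are among the 3 with fewer detected genes.

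Cell cycle genes were again the list furthest from the other genes. Of 43 members 0 passed in edgeR over all genes and 24 adjusted over the list alone, and 42 were positive with a median of 1.36 (camera adjusted p = 5.42e-23, but adjusted p = 0.413 with an estimated correlation). Kif20a, Prc1 and Ube2c stood at 2.29 ± 0.42, 2.39 ± 0.47 and 2.27 ± 0.46. Collagens and elastic fibre genes had a median of 0.34 with 22 of 24 positive (camera adjusted p = 1.04e-05), and Col1a1 stood at 0.87 ± 0.30. Matrix proteases had a median of 0.24 (camera adjusted p = 0.0143), with Timp1 at 1.25 ± 0.29. Interferon-stimulated genes had a median of 0.44 (camera adjusted p = 2.09e-05), led by Ifi27l2a at 1.27 ± 0.36 and Oas2 at 1.29 ± 0.39, and monocyte and macrophage markers a median of 0.33 (camera adjusted p = 8.99e-05), led by Cd68 at 1.15 ± 0.32. Adipocyte markers had a median of 1.27 with 14 of 15 positive (camera adjusted p = 8.99e-05), led by the adipokine genes Retn and Cfd at 2.08 ± 0.64 and 2.46 ± 0.79. All 11 mesothelial markers were negative, with a median of -1.04 (camera adjusted p = 0.000319), led by Krt19 at -1.87 ± 0.53 and Wt1 at -1.48 ± 0.42. For each of these lists other than cell cycle the adjusted p was 0.703 with an estimated correlation, as it was for the cytokine, coagulation, leukocyte adhesion and senescence-associated lists, whose medians were 0.49, 0.16, 0.32 and 0.18. Adjusted over the list alone 4 adipocyte, 2 interferon-stimulated, 2 cytokine, 1 coagulation and 1 matrix protease genes were up, and 2 mesothelial and 1 cytokine genes were down.

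Most of these lists depended on single libraries, with the following medians on the log2 CPM scale. Adipocyte markers scored 0.21 in aging injured 1, within the range of the aging sham libraries, -0.90 to 0.22, and 1.68 in aging injured 2. Their median of 1.04 was 2.21 without aging injured 1, and the list did not pass without aging injured 2 (0.41). Interferon-stimulated genes scored 1.30 and 0.37 in aging injured 1 and 2 and 1.33 in aging sham 2. Their median of 0.72 was 0.32 without aging sham 1, 1.37 without aging sham 2 and 1.11 without aging injured 2, and the list did not pass without aging injured 1 (0.19). Collagens did not pass without aging injured 2 (0.07 against 0.33), and were at 0.51 without aging injured 1. The monocyte and macrophage median of 0.36 was 0.17 without aging sham 1. Cytokines did not pass without aging injured 1 (0.49) and were at 0.21 without aging sham 1. Matrix proteases did not pass without aging injured 1 (0.29) or 2 (0.21), nor did senescence-associated genes (0.27 and 0.04, and 0.13 without aging sham 1, against 0.15) or leukocyte adhesion molecules (0.36 and 0.26, and 0.08 without aging sham 1, against 0.34). The coagulation median of 0.14 turned to -0.12 without aging injured 1, was 0.22 without aging injured 2, and the list did not pass without young sham 1 (0.14) or aging sham 1 (0.11). Of the 11 lists 5 passed with the added term for the 3 libraries with fewer detected genes, which within groups rests on young sham 1. Medians under it of 0.60 for cytokines, 0.42 for coagulation, 0.15 for leukocyte adhesion, 0.23 for collagens, 0.00 for matrix proteases and 0.03 for senescence-associated genes did not pass. Cell cycle, mesothelial, and monocyte and macrophage lists stayed past the threshold whichever library was left out, the last with the lower median given above.

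Whether injury acted differently at the 2 ages was asked with the interaction, in which edgeR called 0 genes, DESeq2 174, with 24 up and 150 down, and limma-voom 0, with 1523 genes at an unadjusted p under 0.05. The genes with the smallest p, none of which passed, were Zfp442, Med31, Ccz1, Traf4 and Uckl1os, each with an adjusted p of 0.446. Uckl1os overlaps Uckl1, and its reads cannot be told from those of its partner without strand. Of the 78 genes that rose after injury in young valves, 72 had a positive log2 fold change in aging valves and 41 were over 2-fold there, with medians of 2.29 in young and 1.05 in aging valves. The aging libraries are separate from the young ones, but with genes selected on the young values the lower median in aging valves is not a test of the difference. Across genes, which are not independent replicates, the correlation of the log2 fold changes of both ages was 0.028 over all genes and 0.233 over the 15004 genes with a mean CPM of at least 1. Lists that differed by the preset test were cell cycle, with a median interaction of -0.86 (camera adjusted p = 4.72e-05), oxidative phosphorylation at 0.64 (camera adjusted p = 5.69e-08) and cardiomyocyte markers at 0.65 (camera adjusted p = 2.96e-06). Mesothelial markers were at -1.93 (camera adjusted p = 5.01e-05) and adipocyte markers at 1.18 (camera adjusted p = 0.00041). Interferon-stimulated genes were at 0.45, unfolded protein response genes at -0.46, collagens at -0.19 and pan-endothelial markers at 0.14. With an estimated correlation each of the 9 lists had an adjusted p of 0.877. Adjusted over the list alone 8 mesothelial markers were down.

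Several of these differences also rested on single libraries, again on the log2 CPM scale. The adipocyte value of 1.09 was 2.03 without aging injured 1, 0.54 without young injured 1 and 0.28, not past the threshold, without aging injured 2. The interferon-stimulated value of 0.63 was 0.25, not past the threshold, without aging injured 1, 1.01 without aging injured 2, 0.24 without aging sham 1 and 1.19 without aging sham 2. The pan-endothelial value of 0.30 turned to -0.22 without young injured 1 and did not pass without young sham 3 (0.06), aging sham 1 (0.08) or aging injured 1 (0.16). It was 0.15 without young sham 2 and 0.47 without young injured 3. The collagen value of -0.30 did not pass without aging injured 1 (-0.02), aging sham 3 (-0.22), young injured 3 (-0.22) or young sham 2 (-0.25), and was -0.64 without aging injured 2 and -0.47 without young injured 1. The oxidative phosphorylation value of 0.79 was 0.51 without young injured 1 and 1.22 without young injured 3. The cardiomyocyte value of 1.22 was 1.97 without young injured 3, and the mesothelial value of -1.92 was -1.25 without young sham 3.

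**Figure D2:**
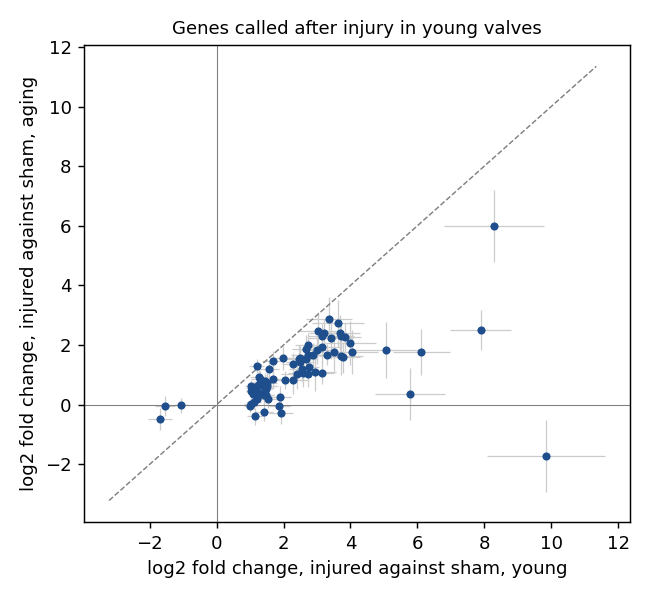
Log2 fold change of injured against sham valves in aging mice (vertical axis) against that in young mice (horizontal axis) for the 81 genes called in young valves, with SE bars and a dashed line of equal change. Of the 78 genes that rose in young valves 72 lie above 0 on the vertical axis, and the values beyond 5 on the horizontal axis belong to genes with few or no counts in young sham valves, whose fitted fold changes depend on the prior count.

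Averaged over both ages, injury was followed by a rise of 84 genes and a fall of 31. Of the 10 rising genes with the smallest p, clone-like symbols left out, 6 were on the cell cycle list. Ccna2 rose 8.08-fold (adjusted p = 0.00364), Top2a 5.61-fold, Timp1 4.03-fold, Ube2c 8.34-fold, Kif20a 6.57-fold and Uhrf1 4.29-fold. Fam83d rose as well, and as it had 1 count over the young sham libraries no fold is given for it. Prc1, which bundles spindle microtubules, rose by 2.81 ± 0.32 on the log2 scale, Mki67, the proliferation marker Ki-67, rose 5.14-fold, and the scaffold gene Iqgap3 4.82-fold. Of the 43 cell cycle genes 21 rose, or 34 adjusted over the list alone (median 1.83, camera adjusted p = 1.97e-46, adjusted p = 0.0702 with an estimated correlation). The collagens had a median of 0.53 (camera adjusted p = 2.72e-12, adjusted p = 0.244 with an estimated correlation), and on the log2 CPM scale 0.51, or 0.30 without aging injured 2. By the preset test 12 lists passed upward and 4 downward, and several rested on single libraries. Among those upward, log2 CPM medians were 0.31 for interferon-stimulated, 0.86 for adipocyte and 0.19 for senescence-associated genes. Interferon-stimulated genes did not pass without aging sham 1 (0.14), and were at 0.59 without aging sham 2 and 0.08 without aging injured 1. Adipocyte markers did not pass without young injured 3 (0.65). Without aging injured 1 and 2 they were at 1.33 and 0.31, and senescence-associated genes at 0.35 and 0.05. Among those downward, log2 CPM medians were -0.40 for cardiomyocyte markers, -0.24 for oxidative phosphorylation and -0.26 for smooth muscle markers. Cardiomyocyte markers did not pass without young sham 3 (-0.29), young injured 1 (-0.21) or 2 (-0.22), or aging sham 1 (-0.17). Oxidative phosphorylation did not pass without the same libraries, at -0.17, -0.12, -0.17 and -0.14. Without young injured 3 these lists were at -0.77 and -0.45. Smooth muscle markers did not pass without young sham 1 (-0.12), young injured 3 (-0.12) or aging sham 2 (-0.23). They were at -0.44 without young sham 3. Outside the cell cycle and collagen lists Ccl2 rose by 2.08 ± 0.37, Procr by 2.02 ± 0.40, the lysosomal macrophage marker Cd68 by 1.11 ± 0.22 and Cthrc1 by 2.27 ± 0.31 on the log2 scale. The fall was mostly of genes with few counts. Of the 31 genes that fell, 26 had 3 counts or fewer over both aging injured libraries and 20 had 0, and both are libraries with fewer detected genes. Among them Fam71f2, Olfr78, Abcc6, Rgs1 and Crabp1 had 0 counts over the aging injured and 69, 72, 40, 64 and 51 over the aging sham libraries. Against a bound of 3 counts these were at least 14.8-, 15.4-, 8.58-, 13.7- and 10.9-fold lower in counts. Zfp442, Clec4g and Lhx9 had 1, 1 and 2 counts over the aging injured libraries. Their ratios in aging valves were 135, 83.0 (exact 95% interval 14.6 to 3300) and 69.5 (19.0 to 578). These bounds and intervals cover counting error only. Among 1245 genes with a median of 1 to 2 CPM in the libraries without fewer detected genes, at most 0.96% were at 0 in any of those. In aging injured 1 and 2 the share was 6.99% and 4.10%, and 5.94% in young sham 1. The bounds therefore do not establish lower levels in the valves. Fxyd7 and Atg9b, at higher counts, fell by 1.42 and 2.40 on the log2 scale. The count of 115 was 38 without young injured 2, 52 without young sham 2, 40, 45 and 51 without aging sham 1, 2 and 3, and 284 without aging injured 1. The balance of directions turned without aging injured 1, with 116 up and 168 down, without aging injured 2, with 77 up and 84 down, and with DESeq2, with 190 up and 212 down, whereas limma-voom called 69 up and 4 down. The count was 402 with DESeq2, 73 with limma-voom, 38 with limma on the logarithm of RPKM plus 1, and 288 with the added term for the 3 libraries with fewer detected genes, with 75 of these among the 115. Of the 161 called without aging injured 2, 71 were among the 115.

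Age in sham valves was compared to ask what differed by age without wire injury. These valves were taken after sham surgery, and valves without surgery were not sampled. Differences present before surgery therefore cannot be separated from differences in the response to sham surgery. In aging sham valves 4 genes rose and 1 fell. Igfbp2, a binding protein of insulin-like growth factors (ENSMUSG00000039323, chromosome 1, 72824503 to 72852474), rose 9.54-fold, from 7.26 ± 2.65 to 69.6 ± 19.5 CPM (SD, n = 3 each), with an adjusted p of 0.0168. Efhd1, a mitochondrial calcium-binding protein, rose 2.45-fold, from 70.7 ± 10.2 to 173 ± 17.2 CPM (n = 3 each). The scavenger receptor family gene Cd163l1 rose 4.55-fold and Vsig4, a complement receptor of resident macrophages, 2.58-fold, both with an adjusted p of 0.063. Angptl1, an angiopoietin-like secreted protein, fell by 2.02 ± 0.27 on the log2 scale, from 15.1 ± 2.51 to 3.71 ± 1.16 CPM (n = 3 each).

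Among the lists, all 26 cardiomyocyte markers were negative (median -1.24, camera adjusted p = 8.76e-12, adjusted p = 0.490 with an estimated correlation), with Ckm at -1.52 ± 0.52 and Myh6 at -1.07 ± 0.48. So were all 28 oxidative phosphorylation genes, 4 of them down adjusted over the list alone (median -0.79, camera adjusted p = 2.66e-13, adjusted p = 0.490 with an estimated correlation). Cardiomyocyte scores were 0.34, 0.99 and 1.46 in young sham 1, 2 and 3 and 0.63, -1.63 and -0.79 in aging sham 1, 2 and 3. Oxidative phosphorylation scores were 0.10, 0.59 and 0.91 against 0.15, -0.53 and -0.51. On both lists aging sham 1 thus lay above young sham 1, and the groups overlapped. Immediate early and heat shock genes had a median of -0.96 with 1 of 20 positive, 0 called over all genes and 10 adjusted over the list alone (camera adjusted p = 1.62e-10, adjusted p = 0.475 with an estimated correlation). Zfp36 and Atf3 stood at -0.83 ± 0.19 and -2.84 ± 0.65, and Hspa1a and Hspa1b, near-identical copies whose reads cannot be assigned with certainty, at -3.54 ± 0.82 and -3.69 ± 0.82. This list had its highest score, 1.26, in young sham 1, a library with fewer detected genes. Mesothelial markers had a median of 1.83 with 10 of 11 positive and 8 adjusted over the list alone (camera adjusted p = 1.23e-07, adjusted p = 0.475 with an estimated correlation), led by Upk1b at 1.83 ± 0.37 and Krt19 at 1.87 ± 0.46. All 17 lymphocyte markers were positive (median 1.30, camera adjusted p = 2.98e-05, adjusted p = 0.485 with an estimated correlation), with Cd3g at 2.64 ± 0.99 and Ighm at 0.90 ± 0.52. Young sham 1, a library with fewer detected genes, scored -1.99 for this list, and young sham 2 and 3 scored -0.57 and 0.49. Interferon-stimulated genes had a median of 0.72 (camera adjusted p = 0.00497, adjusted p = 0.806 with an estimated correlation), where aging sham 2 scored 1.33 and aging sham 1 and 3 scored -0.56 and -0.21. This median on the log2 CPM scale, 0.54 with all libraries, turned to -0.04 without aging sham 2, was 0.92 without aging sham 1, and did not pass without young sham 2 (0.43). The immediate early and heat shock median of -0.90 was -0.56 without young sham 1. Of the 18 senescence-associated genes Igfbp2 rose, and 3 did adjusted over the list alone, the others being Mmp3, at 2.83-fold, and Cdkn2a, at 1.58 ± 0.41 on the log2 scale (median 0.29, camera adjusted p = 0.000643, adjusted p = 0.475 with an estimated correlation). Smaller medians past the preset threshold were 0.41 for monocyte and macrophage, 0.55 for leukocyte adhesion, 0.35 for coagulation, 0.24 for unfolded protein response, 0.59 for smooth muscle, -0.12 for proteoglycan and -0.09 for fibroblast genes. Their adjusted p-values with an estimated correlation were 0.641, 0.490, 0.641, 0.615, 0.641, 0.641 and 0.475, and 3 leukocyte adhesion molecules were up adjusted over the list alone. On the log2 CPM scale, leukocyte adhesion was at 0.38 against 0.60 without young sham 2, and coagulation at 0.27 against 0.43 without aging sham 2. Coagulation did not pass without young sham 2 (0.30), nor did unfolded protein response genes (0.17 against 0.27, and 0.44 without young sham 3). Smooth muscle markers did not pass without young sham 3 (0.28 against 0.68), proteoglycans without young sham 1 (-0.09) or aging sham 2 (-0.10) or with the added term for 3 libraries (-0.09), and fibroblast markers without aging sham 1 (-0.06 against -0.12, and -0.20 without aging sham 2). The count of 5 genes was 1 without young sham 1 or 2, 1 without aging sham 2 or 3, 3 without aging sham 1, 2 without aging injured 1 or 2, 9 without young injured 1 or 2 and 10 without young injured 3, and it was 200 with DESeq2. Without young sham 3 the calls were 2 up and 4 down, with 3 among the 5. With the cardiomyocyte score as a covariate 2 of the 5 genes were called, and 9 of the 14 lists stayed past the threshold. The cardiomyocyte list, counted among the 14, supplies the score, so its own result there was set by construction. When only the sham libraries were fitted 13 genes were called, 2 of them among the 5. With quality weights, a setting added after seeing the data, 294 rose and 517 fell.

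**Figure D3:**
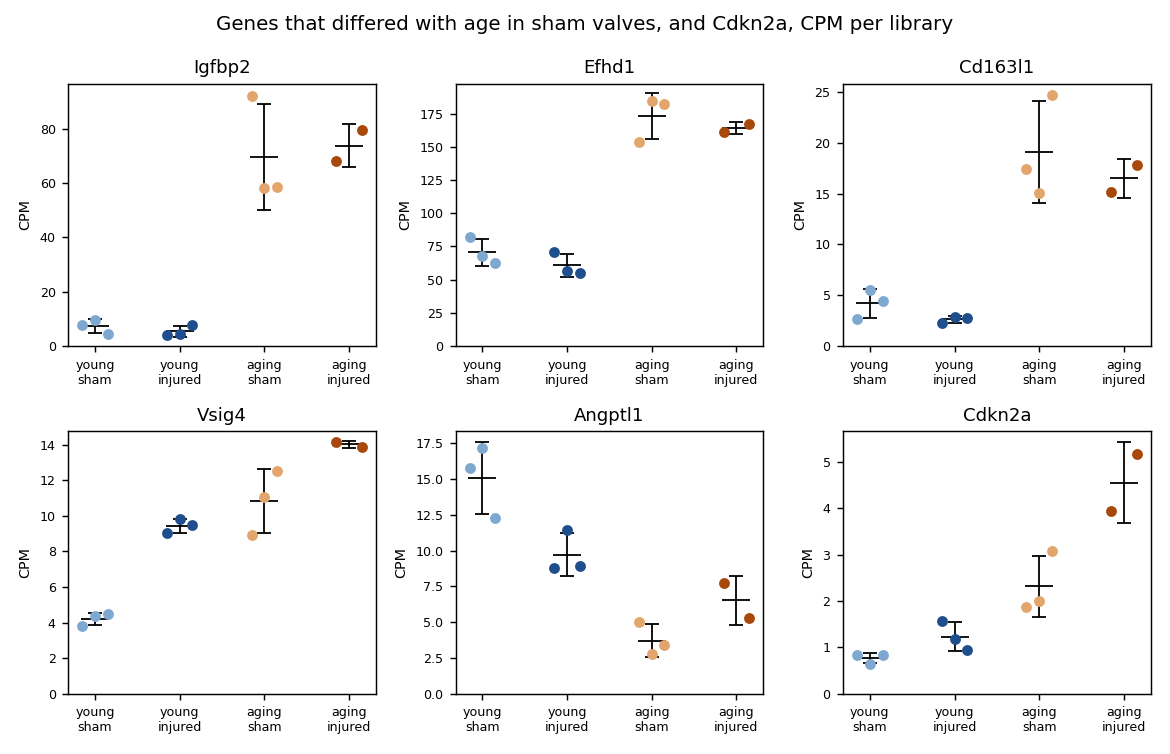
CPM (linear axis) of the 5 genes called between aging and young sham valves and of Cdkn2a, which did not pass, by group, where points are libraries and bars give the mean and SD of 3 libraries, or of 2 for aging injured. Igfbp2 averaged 69.6 CPM in aging sham and 73.8 CPM in aging injured valves, against 7.26 and 5.49 CPM in young sham and young injured valves.

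In injured valves 9 genes rose with age and 3 fell. Igfbp2 and Cd163l1 rose 13.4-fold and 6.31-fold, Efhd1 rose by 1.43 ± 0.16 on the log2 scale, and Igfbp2 averaged 5.49 ± 2.04 CPM in young injured (n = 3) and 73.8 ± 8.02 CPM in aging injured valves (n = 2). Sphkap, an anchoring protein of protein kinase A, rose 5.20-fold, Ccdc3, a secreted protein, 2.54-fold, and Lepr, the leptin receptor, 2.58-fold. Rab6b rose by 1.07 ± 0.17 on the log2 scale, and the circadian repressor gene Ciart rose 3.01-fold. Fap, a protease of activated fibroblasts, fell by 1.59 ± 0.24 on the log2 scale, from 21.5 ± 5.58 to 7.13 ± 0.79 CPM, and Zfp442 had 204 counts over the young and 1 over the aging injured libraries, a ratio of 122 with an exact 95% interval of 21.7 to 4850. The aging injured group was made up of 2 female mice and young injured of 1 male and 2 female mice. All 24 interferon-stimulated genes were positive, with a median of 1.21, 0 called over all genes in the edgeR test and 12 adjusted over the list alone (camera adjusted p = 8.52e-11, adjusted p = 0.782 with an estimated correlation), with Oas2 at 1.60 ± 0.40 and Irf7 at 1.64 ± 0.55. Cell cycle genes had a median of -0.72 with 3 of 43 positive (camera adjusted p = 1.18e-05, adjusted p = 0.782 with an estimated correlation), with Top2a at -1.31 ± 0.36. Adipocyte markers had a median of 1.11, smooth muscle markers of 0.68, immediate early and heat shock genes of -0.67 and senescence-associated genes of 0.30, and their adjusted p was 0.782 with an estimated correlation. Lymphocyte markers had a median of 1.18, monocyte and macrophage markers of 0.37, pan-endothelial markers of 0.20 and collagens of -0.39, and their adjusted p was 0.819 with an estimated correlation. Adjusted over the list alone 3 lymphocyte, 1 monocyte and macrophage, 1 smooth muscle, 1 collagen and 2 senescence-associated genes were up, and 5 immediate early and heat shock, 2 cell cycle, 2 collagen and 1 senescence-associated genes were down. Lymphocyte scores were -0.50 and 1.02 in aging injured 1 and 2, and -0.82, -0.52 and -0.43 in the young injured libraries. Acta2, smooth muscle actin, stood at 1.20 ± 0.34, the macrophage glycoprotein gene Gpnmb at 1.38 ± 0.26, Col12a1 at -1.22 ± 0.22 and Ighm at 2.36 ± 0.57. On the log2 CPM scale the lymphocyte median of 1.03 was 1.62 without aging injured 1, 0.60 without young injured 1 and 0.75, not past the threshold, without aging injured 2. The pan-endothelial median of 0.29 turned to -0.08 without young injured 1, was 0.53 and 0.50 without young injured 2 and 3, and did not pass without aging injured 1 (0.28). Adipocyte markers did not pass without aging injured 2 (0.29 against 0.92), and were at 2.21 without aging injured 1 and 0.32 without young injured 1. Monocyte and macrophage markers did not pass without young injured 1 (0.19 against 0.38). Without aging injured 1 collagens (-0.16 against -0.39) and immediate early and heat shock genes (-0.50 against -0.68) did not pass, interferon-stimulated genes were at 0.75 against 1.15 and senescence-associated genes at 0.51 against 0.30. Senescence-associated genes did not pass with the added term for 3 libraries (0.09). Cell cycle genes were at -0.52 against -0.83 without young injured 2, and smooth muscle markers at 0.48 against 0.77 without young injured 3 and at -0.04 with the added term for the 3 libraries with fewer detected genes.

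The count of 12 genes was 429 without aging injured 1, 121 without aging injured 2, 41 without young sham 1, 6 without young sham 2, 3 without young injured 1, 7 without young injured 3 and 3 without aging sham 3. Most calls were down without aging injured 1, with 101 up and 328 down, without aging injured 2, with 22 and 99, without young sham 1, with 16 and 25, and with DESeq2, with 166 and 433. The count was 599 with DESeq2, 0 when only the injured libraries were fitted and 104 with the added term for the 3 libraries with fewer detected genes. Of these 104 genes 3 were among the 12, so 9 of the 12 lost their call.

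**Figure D4:**
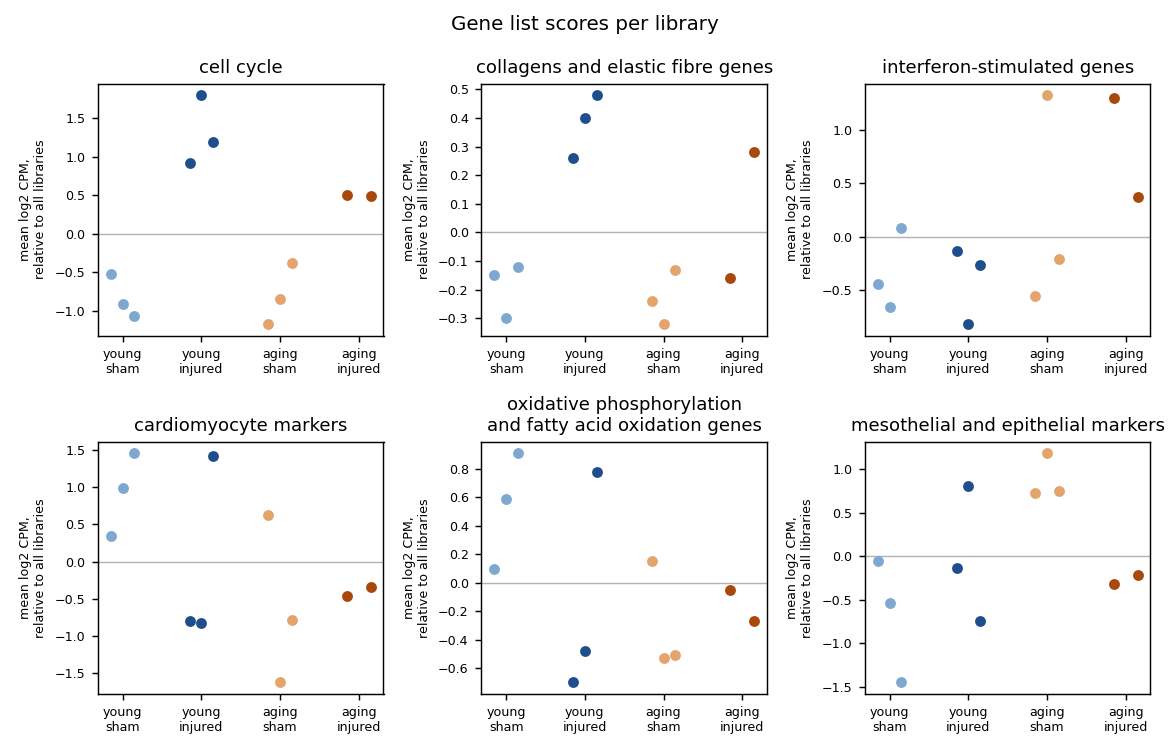
Score of 6 gene lists per library (vertical axis, mean log2 CPM of the list relative to its mean over all libraries), by group, where each point is 1 library. The cell cycle scores of the 3 young injured libraries, 0.92 to 1.80, and of the aging injured ones, 0.50 and 0.49, lie above all sham libraries, and the cardiomyocyte score of young injured 3, 1.43, lies apart from those of young injured 1 and 2.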

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

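The tests of young sham 1 in the cell cycle pattern, of the 3 libraries with fewer detected genes and of the genes far out in aging injured libraries were chosen after the results were seen, and the sex covariate was an added setting.

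The injury effect in aging valves minus that in young valves passed the preset camera threshold for 9 lists, and each had an adjusted p of 0.877 with an estimated correlation. The median differences on the log2 scale were -0.86 for cell cycle genes, 0.45 for interferon-stimulated genes, 0.14 for pan-endothelial markers, -0.19 for collagens and elastic fibre genes and 0.64 for oxidative phosphorylation and fatty acid oxidation genes. They were -0.46 for unfolded protein response genes, 0.65 for cardiomyocyte markers, 1.18 for adipocyte markers and -1.93 for mesothelial and epithelial markers.

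The cell cycle list went up in injured valves of young mice, with a median of 2.20 on the log2 CPM scale and 17 of 43 genes past the thresholds over all genes. Lower cardiomyocyte content or the sex of the mice as the whole cause is argued against by medians of 1.98 with the cardiomyocyte score and 2.26 with sex as a covariate. Young sham 1 is likewise argued against, since the median was 2.33 without it. In each of these settings the list stayed past the camera threshold. The injury itself and a change in the mix of cells other than cardiomyocytes in the valve stay open and were not tested.

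Young sham 1 and both aging injured libraries had fewer detected genes than the other 8. A lower read total is argued against, since after thinning all libraries to the smallest total these 3 had at most 18836 detected genes and the others at least 20406. A candidate explanation is that few starting RNA molecules entered these libraries. Their deviations over 1245 genes at low levels were nearly independent, with a highest pairwise correlation of 0.093, and their spread was at least 1.55 times that of any other library. The median of the other 8 libraries set both the reference of the deviations and the choice of genes. This narrows the spread of those 8 by construction, so the ratio is too high by an unknown amount. As both aging injured libraries are among them, comparisons with that group cannot be separated from this property, and a biological explanation was not tested.

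Among 11903 genes with a median of at least 5 CPM over all libraries, 17 lay in both aging injured libraries beyond all other libraries by 1.5-fold, 3 higher, with Ccl8, Lgals3bp and Traf4, and 14 lower, with Med31, Dhodh and Malt1 among them. Pairs of young sham 1 with an aging injured library gave 10 and 5 such genes, so few starting RNA molecules and a difference of the aging injured valves cannot be told apart. Sex stays open here: 1 of the 17 genes separated the other female from the male libraries in the same direction, but the genes had been chosen for lying beyond libraries of which 5 were female. The pair with most such genes was young sham 3 and young injured 3, with 115, so a pair of libraries from different groups gave more.

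Of the 10 splits of the 6 young libraries into groups of 3, 2 gave at least the 81 genes of the real split, and the highest other gave 272. That split set young sham 1 with young injured 1 and 2 against young sham 2, young sham 3 and young injured 3, and points to a structure of the samples. In these orders the cardiomyocyte scores were 0.34, -0.80 and -0.83 on the first side and 0.99, 1.46 and 1.43 on the second. The split thus parted libraries with lower from those with higher levels of cardiac muscle transcripts. Of the 10 splits of the sham libraries by age 1, the real one, gave 5 genes, and the highest other gave 0. With 10 splits no share under 0.05 can be reached. For injury averaged over age, 2 of 100 splits drawn from 200, the real one with 115 genes included, gave as many. The highest other gave 169, and it parted the young libraries in the same way as the split with 272 genes. The share is under 0.05, but a wrong grouping gave more genes than the real one. The splits therefore cannot separate injury from a structure of the samples, and no conclusion on chance is drawn.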

How the results depend on the processing

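Settings chosen after seeing the data were sex as a covariate, the term for 3 libraries with fewer detected genes, and quality weights. The counts of called genes below moved by over 1.5-fold, and the cause was not tested.

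For injury in young valves (81 genes), DESeq2 gave 268, RPKM plus 0.1 gave 153, only the groups compared 11, the term for 3 libraries 43, quality weights 376, an adjusted p under 0.05 gave 44 and no fold threshold 133, of which the DESeq2 genes shared 79 with the 81. For injury in aging valves (0 genes in edgeR, 1710 at an unadjusted p under 0.05, 0 in limma-voom), no filter gave 1, DESeq2 gave 329, RPKM plus 0.1 and plus 1 each gave 3 and the term for 3 libraries 3. For age in sham valves (5), no filter gave 14, DESeq2 gave 200, limma-voom 2, RPKM plus 0.1 gave 9 and plus 1 gave 22, only the groups compared 13 (2 among the 5), the cardiomyocyte covariate 2, sex 3, the term for 3 libraries 1, quality weights 811 (294 up, 517 down) and an adjusted p under 0.05 gave 2. For age in injured valves (12), no filter gave 38, CPM of at least 1 gave 29, DESeq2 gave 599, RPKM plus 0.1 gave 40 and plus 1 gave 36, sex 7, the term for 3 libraries 104 (3 among the 12), quality weights 1 and an adjusted p under 0.05 gave 6. Only the groups compared gave 0 in edgeR there, where 2425 genes had an unadjusted p under 0.05 with all groups fitted and limma-voom called 11. For the interaction (0 in edgeR, 1523 at an unadjusted p under 0.05, 0 in limma-voom), DESeq2 gave 174 and RPKM plus 0.1 gave 3. For injury averaged over age (115), DESeq2 gave 402, limma-voom 73, RPKM plus 1 gave 38, sex 73, the term for 3 libraries 288 (75 among the 115), quality weights 60, an adjusted p under 0.05 gave 55 and no fold threshold 202.

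Leaving out each library in turn gave 16 to 447 genes for injury in young valves (16 without young injured 2, 447 without young injured 3) and 0 to 261 for injury in aging valves (261 without aging injured 1). It gave 1 to 10 for age in sham valves (10 without young injured 3, and 1 without young sham 1, young sham 2, aging sham 2 or aging sham 3). It gave 3 to 429 for age in injured valves (429 without aging injured 1, and 3 without young injured 1 or aging sham 3), 38 to 284 for injury averaged over age (38 without young injured 2, 284 without aging injured 1) and 0 for the interaction in edgeR. Without 1 aging injured library, the other is assumed to vary like the other groups.

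With the replicate number as a block, age in injured valves gave 4 genes, injury averaged over age 60, and 17 lists were called for injury in aging valves. Deviations of 15 pairs of libraries with the same number correlated by -0.131 to 0.245 and those of 30 other pairs by -0.23 to 0.263. The means were 0.01 and -0.005, so no general link by number was seen, but a link within single pairs cannot be excluded. The highest value with the same number, 0.245, was that of young sham 3 and young injured 3. That pair also shared 115 genes beyond all other libraries. No label says that equal numbers pair mice.

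Lists called were 15, 11, 14, 10, 9 and 16 for injury in young valves, injury in aging valves, age in sham valves, age in injured valves, the interaction and injury averaged over age. With an estimated correlation they were 1, 0, 0, 0, 0 and 1, with fry 5, 0, 0, 0, 0 and 3, and the term for 3 libraries gave 15 for the interaction. Leaving out libraries gave 13 to 17, 6 to 15, 11 to 16, 7 to 15, 7 to 12 and 11 to 18 lists, with 6 for injury in aging valves without either aging injured library. Of the 75 calls, 73 were lost with an estimated correlation, 67 with fry, 12 with the cardiomyocyte covariate, 14 with the term for 3 libraries, which reversed 1 more, and 16 and 14 without aging injured 1 and 2. Of the 11 lists for injury in aging valves 5 passed under that term. The cardiomyocyte list supplies the cardiomyocyte covariate, so results of that list under the covariate were set by construction. Without some library 36 of the 75 calls were lost and 6 medians turned sign, and 20 calls held within 1.5-fold whichever library was left out. The smooth muscle median for injury in young valves turned to 0.02 without young injured 3 and the coagulation median for injury in aging valves to -0.12 without aging injured 1. Pan-endothelial medians reversed without young injured 1. Leaving out libraries they ranged from -0.52 to 0.14 for injury in young valves, -0.08 to 0.53 for age in injured valves and -0.22 to 0.47 for the interaction. The median of interferon-stimulated genes for age in sham valves ranged from -0.04 without aging sham 2 to 0.92 without aging sham 1, and that of smooth muscle markers for age in injured valves reversed to -0.04 under the term for 3 libraries. Of the named gene results 0 reversed, among 388 in most settings, 374 in both RPKM fits, 381 with CPM of at least 1 and 385 with only the groups compared. A reversal was counted only for a gene called in the main fit or under the other setting. Sign changes of genes called in neither were not counted. Calls were lost for 28 named results without young sham 2 and for 27 with only the groups compared.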

Other observations

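The values below were looked up after the results were seen.

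Among 11903 genes with a median of at least 5 CPM over all libraries, young sham 3 and young injured 3 shared 32 genes above and 83 genes below all other libraries by 1.5-fold. Among those above were Nkx2-5 and Csrp3, genes of cardiac muscle, and Hcn4, the channel of pacemaker cells. Among those below were Lmod1, Mylk, Itga8, Kcnmb1 and Tagln of the smooth muscle list and Upk3b and Lrrn4 of the mesothelial list. The cytoskeleton gene Flna and the clock gene Per2 were also below. Smooth muscle scores were -0.65 in young sham 3 and -0.92 in young injured 3, and cardiomyocyte scores 1.46 and 1.43. The mitochondrial share of counts was 13.78% in young sham 3 and 11.06% in young injured 3, and 5.68% and 5.72% in young injured 1 and 2. It was 8.90% and 11.85% in young sham 1 and 2, so this share does not set the pair apart from all others.

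Neutrophil markers differed between injured libraries of young mice, with scores of -0.99, 1.98 and 0.12 on the log2 scale, and the list did not pass (camera adjusted p = 0.470). Of the 16 tested, 6 were up and 1 was down adjusted over the list alone. Adipocyte markers scored 0.21 and 1.68 in the aging injured libraries and -1.24, 0.34 and 0.57 in the young injured ones.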
